A study of Mus musculus with 9 samples.

How the data were processed

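Gene expression was measured on 9 arrays, each hybridised with biotin-labelled total RNA of a single sample, 3 for osteosarcoma lines, 3 for osteoblast cultures and 3 for pre-osteoblast cultures of the Kusa4b10 line. Tumour lines were grown subconfluent and used below passage 8, and osteoblast cultures were differentiated for 21 days, per the labels' protocols. The deposited values are log2 expression levels per probe set, made by the authors with RMA, per the submitters' processing notes, which name the genome build mm9. RMA corrects background, normalizes between arrays and summarises the probes of a probe set, and its version and filters are not given in the sources used here. RMA compresses small differences near background, and normalization between arrays removes any change of total RNA per cell, so each difference is relative to the other genes of the array. Array medians over probe sets differed slightly (7.43 to 7.56). No identical arrays were found: at most 4.33% of the values of any pair within a group were equal.

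The table held 35556 probe sets. Gene names came from the platform annotation: 21789 probe sets had 1 gene symbol, 1621 had several and 12146 had none, and those with several or none were left out of the gene tests. Of the probe sets with 1 symbol, 21698 matched a reference gene table by gene identifier, which changed 0 symbols. For the 999 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used, which left 19938 genes. The reference table names another assembly than mm9, so no coordinates were used. Trp53, Runx2, Spp1, the Bglap genes and Cdkn1a are among the list genes not analysed here.

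Groups, tests, gene lists and the rule for naming genes were fixed before the data were examined. A linear model with 3 group means was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 6 residual and 2.19 prior degrees of freedom), with no filter on level. The tests were two-sided, p values were adjusted by Benjamini-Hochberg over 19938 genes, and genes were called at an adjusted p below 0.05. The 3 pairs of groups and a moderated F test over all groups were tested. Osteosarcoma arrays are single arrays of different lines, so that group's spread is between lines. The labels call the Kusa4b10 cultures independent samples.

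The 31 gene lists were osteoblast transcription factors, bone matrix and mineralisation, Wnt antagonists, Wnt ligands and receptors, beta-catenin target genes, p53 target genes, E2F targets and DNA replication, mitosis, BMP and TGF-beta signalling, Notch pathway, osteoclast regulators, matrix remodelling enzymes, interferon response, hypoxia and glycolysis, cholesterol synthesis, ER protein folding and secretion, imprinted genes, Hox genes, DNA methylation machinery, cyclins with CDK inhibitors and the p53 and RB families, sex-linked transcripts, reference genes, and markers of adipocytes, chondrocytes, muscle and myofibroblasts, fibroblasts and stroma, tendon and periosteum, haematopoietic cells and macrophages, osteoclasts, endothelium and epithelium. Some genes stand on more than 1 list. Lists were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Members past the threshold were counted over all genes and adjusted over the list alone.

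The named genes are Wif1 and Rb1, the 10 largest rises and 10 largest falls per comparison among called genes whose groups do not overlap and whose higher mean exceeds the median level of 7.97 (clone-like names left out), up to 4 called members and 1 other member per list, any Wnt antagonist, and the 10 genes with the widest range over the lines. Further genes outside this rule, the sex-linked gene Kdm5d among them, belong to fixed lists.

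The pipeline was tested on simulated data for the same 19938 genes with 200 changed and the 35 measured mitosis genes raised by 1 log2. Calls of these mitosis genes count in the total of calls, but not among the recovered or false ones. With equal spread in the groups, osteoblasts against pre-osteoblasts recovered 62% of 50 genes changed by 0.5 log2, 86% at 1, 100% at 2 and 98% at 3, with 5.91% of calls false. Osteosarcoma against pre-osteoblasts recovered 44%, 86%, 98% and 92%, with 4.09% false, and osteosarcoma against osteoblasts 48%, 84%, 94% and 98%, with 6.29% false. When each gene kept its own spread in each group, 10.4%, 35.7% and 29.6% of the calls were false in these comparisons, 14.9%, 25.3% and 25.7% with 1 array weight per group, and 10.0%, 9.73% and 17.1% with only the compared groups in the fit. The planned fit was kept, and these shares depend on SDs from 3 arrays and on the 200 changed genes, so they do not carry over to the data as they stand.

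The alternatives were filters on dim genes (means above the median or above the lower quartile), the mean of a gene's probe sets, quantile normalization again, arrays centred on their medians, an intensity trend with a robust prior, only the compared groups in the fit, array weights per group or per array, stricter thresholds, the replicate number as a block, an estimated correlation for camera, and leaving out each array. Where an array was left out, the spread was pooled over the groups. Leaving out osteoblast replicate 2 together with pre-osteoblast replicate 2 was added after the data were examined. Overlaps with shared controls were set against 100 simulations of unchanged groups, and repeated with the pre-osteoblast arrays split between the comparisons in 6 ways and the spread pooled over the groups, added after the data were examined. Shares of differentiation genes called between osteosarcoma and osteoblasts were set against 100 simulations with osteosarcoma at the osteoblast means, each group's own spread and the p thresholds of the data, added after the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.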

Results

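RNA was profiled on 9 single-sample expression arrays, 3 in each of 3 groups. The osteosarcoma group held 3 cell lines, called lines 1, 2 and 3 here, each with 1 array. They were grown from tumours of mice in which Cre recombinase, driven by the osteoblast-lineage promoter Osx, deletes floxed alleles of p53 and Rb. The labels call all of these lines fibroblastic. The other groups came from Kusa4b10, a mouse bone marrow stromal cell line. Pre-osteoblasts were undifferentiated Kusa4b10 cultures, and osteoblasts were Kusa4b10 cultures kept for 21 days in medium with ascorbate. The labels call these cultures independent samples. They are all of 1 line, and the spread between them is that of cultures of this line. In both osteosarcoma comparisons, tumour state therefore cannot be told apart from line of origin or culture history. Between osteoblasts and pre-osteoblasts, differentiation cannot be told apart from time in culture, medium or growth state. Values are log2 expression levels, and 19938 genes were tested. The median level of the probe sets on an array lay between 7.43 and 7.56, and the number of arrays, 3 per group, limits the precision of each comparison. Differences are given in log2 with the standard error of the fit, and adjusted p values come from limma with Benjamini-Hochberg adjustment.

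Rb1, which encodes the retinoblastoma protein deleted in the tumour model, was measured at 9.26, 9.67 and 9.85 in lines 1, 2 and 3. It was at 9.28, 9.28 and 9.17 in the pre-osteoblast cultures and at 10.65, 10.63 and 10.64 in the osteoblast cultures. Rb1 was higher in osteoblasts than in pre-osteoblasts by 1.40 ± 0.13 (adjusted p = 2.26e-04) and lower in osteosarcoma than in osteoblasts (-1.05 ± 0.13, adjusted p = 7.67e-04). The difference between osteosarcoma and pre-osteoblasts, 0.35 ± 0.13, did not pass the test (adjusted p = 0.0965), although without osteosarcoma line 1 it was 0.52 with an adjusted p of 0.00310. The position of the probes relative to the deleted part of the gene was not used here, so this level does not check the deletion. Trp53 was not analysed here. Cdkn2a, which encodes the p16Ink4a and p19Arf tumour suppressors, was 20.8-fold higher in osteosarcoma than in pre-osteoblasts (4.38 ± 0.18, adjusted p = 6.85e-06) and 21.9-fold higher than in osteoblasts (4.45 ± 0.18, adjusted p = 5.00e-06).

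Wif1, a secreted antagonist that binds Wnt ligands, is the gene the series is about, and the comparison asks whether its level follows the stage of differentiation. Its mean level was 6.91 ± 0.20 (SD, n = 3) in pre-osteoblasts, 8.62 ± 1.15 (SD, n = 3) in osteoblasts and 6.88 ± 0.46 (SD, n = 3) in osteosarcoma. The single values were 7.14, 6.80 and 6.79 in pre-osteoblasts, 7.94, 9.95 and 7.97 in osteoblasts, and 6.66, 6.56 and 7.41 in lines 1, 2 and 3. Wif1 was 3.27-fold higher in osteoblasts than in pre-osteoblasts (1.71 ± 0.51, adjusted p = 0.0394) and lower in osteosarcoma than in osteoblasts (-1.74 ± 0.51, adjusted p = 0.0357). All 3 osteoblast cultures lay above all 3 pre-osteoblast cultures and above all 3 lines. Between osteosarcoma and pre-osteoblasts the difference was -0.03 ± 0.51 (adjusted p = 0.975), and 0.02 with the arrays centred or normalized again. Without osteoblast replicate 2, the highest culture, the differences were 1.04 (adjusted p = 0.0225) and -1.08 (adjusted p = 0.0191). The call between osteoblasts and pre-osteoblasts was lost without osteosarcoma line 1 (adjusted p = 0.0565), without pre-osteoblast replicate 1 (0.0751), 2 (0.108) or 3 (0.109), and when only these groups entered the fit (0.0566). Adding the replicate number as a block to a fit of these groups also lost the call (adjusted p = 0.0574). It was also lost with osteoblast replicate 2 and pre-osteoblast replicate 2 both left out (0.99, adjusted p = 0.0712), a setting chosen after the data were seen. The call between osteosarcoma and osteoblasts was lost without osteosarcoma line 1 (adjusted p = 0.0989) or 2 (0.0874), without pre-osteoblast replicate 1 (0.0535), 2 (0.0570) or 3 (0.0589), when only these groups entered the fit (0.0945) and with 1 array weight per group (0.0740).

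**Figure D1:**
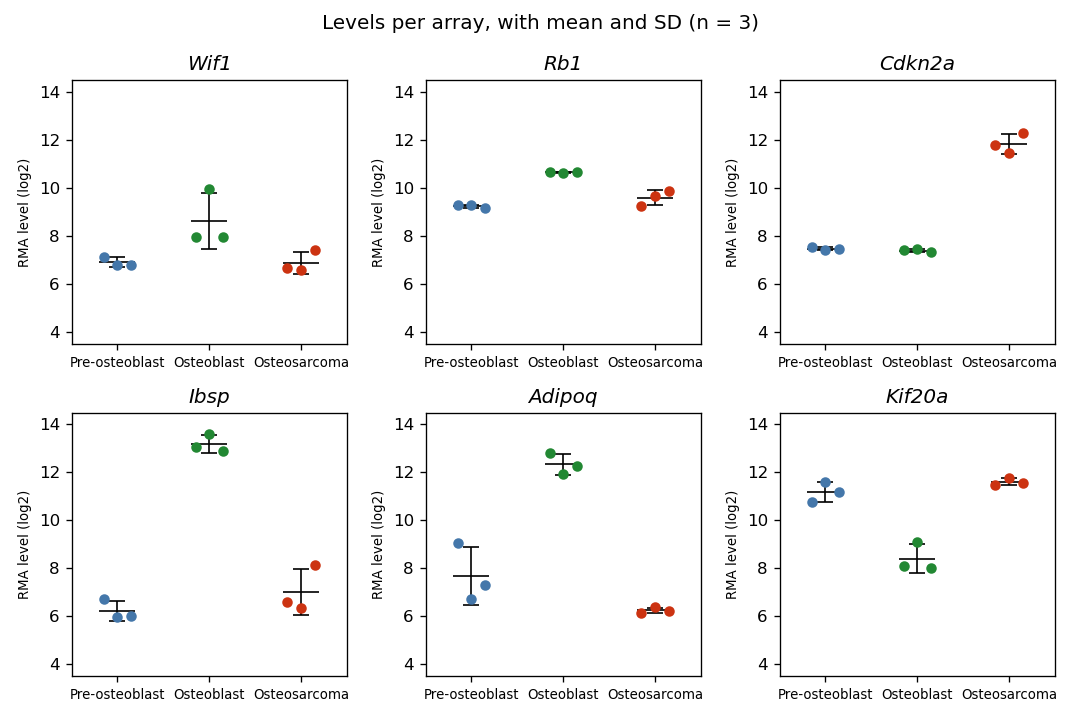
Array levels on the log2 scale (vertical axis) of Wif1, Rb1, Cdkn2a, Ibsp, Adipoq and Kif20a in pre-osteoblasts, osteoblasts and osteosarcoma lines (horizontal axis). Each point is 1 array, drawn in the order of its replicate number, the long bar is the group mean and the whiskers are 1 SD (n = 3). Wif1 lies at 7.94 to 9.95 in osteoblasts and at 6.56 to 7.41 in the other groups.

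The arrays grouped by their labels. Correlations across genes were 0.993 to 0.998 among osteoblasts, 0.994 to 0.997 among pre-osteoblasts and 0.982 to 0.987 among the osteosarcoma lines, against 0.950 to 0.970 between arrays of different groups. The median SD of a gene was 0.118 in osteosarcoma, 0.0823 in osteoblasts and 0.0872 in pre-osteoblasts. The first principal component held 46.3% of the variance and set osteoblasts (39.8 to 51.5) apart from osteosarcoma (-37.6 to -30.9). The second component, with 33.8%, set pre-osteoblasts (-43.3 to -37.8) apart from the rest. Osteoblast replicate 2 stood at 39.8 on the first component and the other osteoblast cultures at 51.4 and 51.5. Against those cultures its mitosis genes were higher by a median of 1.10, bone matrix genes by 0.47 and cholesterol synthesis genes by 0.51, while its adipocyte markers differed by -0.40 and its interferon response genes by -0.41.

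The comparison of osteoblasts with pre-osteoblasts sets Kusa4b10 cultures after 21 days in medium with ascorbate against undifferentiated ones. Osteoblasts expressed far more Ibsp, the bone sialoprotein gene (6.97 ± 0.45, 125-fold, adjusted p = 4.61e-05), and more of the mineralisation genes Dmp1 (4.26 ± 0.18), Phospho1 (4.14 ± 0.21) and Phex (3.81 ± 0.39). Also higher in these cultures were Car3, carbonic anhydrase 3 (6.80 ± 0.17, 112-fold), and the fat cell genes Cd36, a fatty acid transporter (5.28 ± 0.33), the hormone Retn (4.69 ± 0.16) and Adipoq, adiponectin (4.65 ± 0.52). The mitotic kinesin Kif20a (-2.77 ± 0.30) and the isoprenoid enzyme Idi1 (-3.76 ± 0.32) fell. The largest falls also held the Trim30 family member Trim30d (-4.04 ± 0.43, 16.5-fold lower), the hyaluronan synthase Has2 (-3.63 ± 0.53), Apol10b (-3.55 ± 0.17), the cornified envelope gene Sprr1a (-3.54 ± 0.30), Clca3a1 (-3.50 ± 0.15) and P-cadherin, Cdh3 (-3.42 ± 0.16). Further large rises were the laminin chain Lama4 (6.09 ± 0.53), the proteoglycan Srgn (5.86 ± 0.29), the small proteoglycans Lum (5.32 ± 0.49) and Dcn (5.02 ± 0.47), Cd200 (5.09 ± 0.44) and Itm2a (5.09 ± 0.38). For each of these genes the 3 arrays of the higher group lay above the 3 of the lower group.

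In total 5202 genes changed (26.1%), 2049 higher and 3153 lower in osteoblasts, of which 501 and 742 changed at least 2-fold. Of 30 bone matrix and mineralisation genes, 13 rose, the same number adjusted over the list alone (camera, up, adjusted p = 1.19e-04, and adjusted p = 0.547 with an estimated correlation). That count was 8 without pre-osteoblast replicate 1 or 2, and 12 rose and 4 fell without osteoblast replicate 2. Of 15 adipocyte markers, 10 rose, the same adjusted over the list alone (adjusted p = 3.90e-08, and adjusted p = 0.492 with an estimated correlation). The lipid droplet gene Plin1 rose by 3.00 ± 0.27. Lipoprotein lipase, Lpl, was at 0.79 ± 0.47 and did not pass (adjusted p = 0.281, and 0.0236 without osteosarcoma line 2). Of 24 genes of protein folding and secretion in the endoplasmic reticulum, 19 rose and 1 fell, the same adjusted over the list alone (adjusted p = 1.98e-13, and adjusted p = 0.452 with an estimated correlation). Among them were Sdf2l1 (2.49 ± 0.17), the stress transcription factor Ddit3 (2.47 ± 0.25) and Dnajb9 (2.37 ± 0.21). The single fall was lost without osteosarcoma line 1 or any 1 Kusa4b10 array. All 35 measured mitosis genes fell, also when adjusted over the list alone, by a median of -2.12 (adjusted p = 1.17e-16, and adjusted p = 0.547 with an estimated correlation). Among them were Bub1b (-2.75 ± 0.35) and Plk1 (-2.56 ± 0.35). Of 45 E2F targets and DNA replication genes, 33 fell, and 34 fell and 1 rose adjusted over the list alone (adjusted p = 7.39e-11, and adjusted p = 0.547 with an estimated correlation). Among them were E2f8 (-2.30 ± 0.38), Rrm2 (-2.19 ± 0.40) and Mcm5 (-1.98 ± 0.34). Of 19 cholesterol synthesis genes, 18 fell, the same adjusted over the list alone (adjusted p = 8.31e-15, and adjusted p = 0.452 with an estimated correlation). Among them were Cyp51 (-2.94 ± 0.33) and Stard4 (-2.85 ± 0.14), while Ebp was at 0.24 ± 0.14.

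Of 27 interferon response genes, 10 fell and 1 rose, and 11 fell and 1 rose adjusted over the list alone (adjusted p = 9.67e-04, and adjusted p = 0.643 with an estimated correlation), with the chemokine Cxcl10 at -2.83 ± 0.44 and the antiviral enzyme Oas3 at -2.18 ± 0.37. The number that fell was 3 without osteoblast replicate 1 or 2 or pre-osteoblast replicate 1 or 3, and 5 without osteoblast replicate 3, while the rise was lost without osteoblast replicate 1 or 3 or pre-osteoblast replicate 2. Wnt ligands and receptors gave 10 of 44 higher and 4 lower, and 10 and 5 adjusted over the list alone (adjusted p = 0.0407, and adjusted p = 0.547 with an estimated correlation). Among them were the Wnt agonist Rspo3 (3.15 ± 0.26), Lrp4 (1.83 ± 0.20) and the receptor Fzd2 (-1.25 ± 0.18). The call for this list was lost without osteoblast replicate 2 (adjusted p = 0.123) or pre-osteoblast replicate 1 (0.0581). Of 21 beta-catenin target genes, 6 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.0159, and adjusted p = 0.547 with an estimated correlation). Among them were Tnfrsf19 (2.50 ± 0.39) and Myc (0.95 ± 0.14). The single fall was lost without osteoblast replicate 1 or 2 or pre-osteoblast replicate 1 or 2, and the call for the list without osteoblast replicate 2 (adjusted p = 0.0816). Of 20 hypoxia and glycolysis genes, 7 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.0206, and adjusted p = 0.547 with an estimated correlation). Among them were Pfkfb3 (1.90 ± 0.23) and hexokinase 2, Hk2 (1.40 ± 0.06). The number that fell was 4 without osteoblast replicate 2, 1 without pre-osteoblast replicate 3, and 0 without osteoblast replicate 1 or 3 or pre-osteoblast replicate 2. The call for this list, too, was lost without osteoblast replicate 2 (adjusted p = 0.0816). Of 12 reference genes, which are often used to scale such data, 6 fell, and 7 fell adjusted over the list alone (adjusted p = 0.0203, and adjusted p = 0.452 with an estimated correlation), with Tubb5 at -0.56 ± 0.08 and Gusb at -0.47 ± 0.10. With an estimated correlation camera called 0 lists in each comparison, and 3 of 31 had an unadjusted p below 0.05 between osteoblasts and pre-osteoblasts, 1 between osteosarcoma and pre-osteoblasts and 3 between osteosarcoma and osteoblasts.

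Among 24 Wnt antagonists, 5 were higher and 2 lower, the same adjusted over the list alone, without a call for the list (adjusted p = 0.150). Besides Wif1, Dkk1 (0.79 ± 0.13), the osteocyte gene Sost (0.52 ± 0.10), Sfrp4 (2.70 ± 0.65) and Nkd2 (1.46 ± 0.38) rose, and Sfrp1 (-2.70 ± 0.71) and Sfrp2 (-1.80 ± 0.31) fell. The number higher was 2 without pre-osteoblast replicate 2 or 3. The number lower was 1 without osteoblast replicate 1 or 3 or any 1 pre-osteoblast replicate, where Sfrp1 had adjusted p values of 0.0682, 0.0892, 0.0747, 0.0644 and 0.0636. Nkd2 was lost without pre-osteoblast replicate 2 (0.0665) or 3 (0.0826), and Sfrp4 without osteoblast replicate 1 (0.0517) or 2 (0.0521) or pre-osteoblast replicate 2 (0.0616) or 3 (0.0586). Of 15 osteoblast transcription factors, 7 were higher and 3 lower, and 7 and 5 adjusted over the list alone (adjusted p = 0.207), with a median of -0.09, a mean of 0.36 and an upward test direction. Mef2c (3.06 ± 0.32), Hey1 (1.80 ± 0.14) and Zfp521 (1.55 ± 0.19) rose. Sp7, which encodes osterix, was 1.66 ± 0.51 higher (adjusted p = 0.0456), a call lost without osteosarcoma line 2 (0.0545). It was also lost without osteoblast replicate 1 (0.0804) or 2 (0.107) and without pre-osteoblast replicate 1 (0.0543), 2 (0.128) or 3 (0.136). There were 6 factors higher and 5 lower without osteosarcoma line 2.

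Further lists gave no call in the comparison of osteoblasts with pre-osteoblasts. Of 40 p53 target genes, 9 fell and 4 rose, 11 and 4 adjusted over the list alone (adjusted p = 0.241), with Ckap2 at -2.10 ± 0.31, and 14 fell without osteosarcoma line 3. BMP and TGF-beta signalling gave 8 of 35 higher and 7 lower, 9 and 7 adjusted over the list alone (adjusted p = 0.241). The matrix protein gene Tgfbi (-3.13 ± 0.52) fell and the BMP antagonist Chrdl1 (2.81 ± 0.35) rose. In the Notch pathway 2 of 20 were higher and 3 lower, 4 and 4 adjusted over the list alone (adjusted p = 0.816), with a median of -0.01, a mean of 0.13 and an upward test. The target gene Hes1 rose by 2.80 ± 0.37, and the glycosyltransferase gene Lfng changed by -1.87 ± 0.20. Matrix remodelling enzymes gave 8 of 30 higher and 6 lower, 9 and 7 adjusted over the list alone (adjusted p = 0.207), with the protease inhibitor Timp3 at 1.98 ± 0.13. Imprinted genes gave 5 of 22 higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.179), with Plagl1 at 1.16 ± 0.20. Without pre-osteoblast replicate 3, 3 were higher, and the fall was lost without osteoblast replicate 1 or 3 or pre-osteoblast replicate 2. Of 18 genes of the DNA methylation machinery, 6 fell and 2 rose, 6 and 3 adjusted over the list alone (adjusted p = 0.816). The maintenance methyltransferase Dnmt1 was at -1.32 ± 0.21 and Gadd45a at 3.83 ± 0.33; 3 fell without osteoblast replicate 1 or 3, and the list median of -0.03 turned positive with quantile normalization again.

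Osteoclast regulators gave 3 of 15 higher and 4 lower in osteoblasts, 4 and 5 adjusted over the list alone (adjusted p = 0.852), with Sema3a at 2.06 ± 0.24. Their median was -0.02, positive with quantile normalization again, their mean -0.16 and the test upward. The number lower was 2 without osteoblast replicate 3 or pre-osteoblast replicate 2 and 1 without pre-osteoblast replicate 3. Hox genes gave 6 of 37 lower and 1 higher, 5 and 1 adjusted over the list alone (adjusted p = 0.376), with Hoxa3 at -0.73 ± 0.13. Without osteosarcoma line 1 these counts were 8 and 3, and without line 2 they were 9 and 2. Fibroblast and stromal markers gave 6 of 26 higher and 5 lower, the same adjusted over the list alone (adjusted p = 0.816), with the protease gene Fap at 4.13 ± 0.24 and Nt5e at 3.26 ± 0.38. The number lower was 3 without osteoblast replicate 2, 2 without replicate 1, and 1 without osteoblast replicate 3 or pre-osteoblast replicate 1 or 3. Of 17 cyclins, CDK inhibitors and p53 and RB family genes, 5 fell and 2 rose, the same adjusted over the list alone (adjusted p = 0.385). Rbl1 (-1.19 ± 0.16) and Trp63 (-1.26 ± 0.11) fell, and 3 fell without osteoblast replicate 3. Of 8 sex-linked transcripts, 2 fell, the same adjusted over the list alone (adjusted p = 0.852). That count was 0 without osteoblast replicate 1 or pre-osteoblast replicate 2, and 1 without osteoblast replicate 3 or pre-osteoblast replicate 1. The median of the sex-linked list, -0.01, turned positive with quantile normalization again.

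Osteosarcoma lines were compared with pre-osteoblasts to set the tumour cells against the undifferentiated state of Kusa4b10. The lines expressed more of the osteoblast cadherin Cdh11 (5.34 ± 0.17, 40.5-fold, adjusted p = 3.80e-06), of Thy1 (4.82 ± 0.30, 28.3-fold), a surface marker of stromal cells, of Gpx3 (4.71 ± 0.40), of the complement inhibitor Serping1 (4.69 ± 0.55), of Slit2 (4.63 ± 0.28) and of Lama4 (4.43 ± 0.53). The largest falls were Trim30d (-5.35 ± 0.43, 40.8-fold lower), Brinp3 (-5.02 ± 0.12), Clca3a1 (-4.74 ± 0.15), Trim30a (-4.41 ± 0.71), Sprr1a (-4.30 ± 0.30), Bves (-4.25 ± 0.36) and the T cell costimulator Cd80 (-4.11 ± 0.35), which is also on the p53 list. All 3 lines lay on the same side of all 3 pre-osteoblast cultures for each of these genes.

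In this comparison 4686 genes changed (23.5%), 1986 higher and 2700 lower in osteosarcoma, a balance that turned to 2419 higher and 2262 lower with the arrays centred on their medians and to 2561 and 2427 with quantile normalization again. Of the 1986 and 2700 genes, 433 and 480 changed at least 2-fold. Of 40 p53 target genes, 21 fell and 2 rose, and 22 fell and 4 rose adjusted over the list alone (adjusted p = 9.85e-05, and adjusted p = 0.615 with an estimated correlation). Among them were Eda2r (-2.63 ± 0.27) and the epoxide hydrolase Ephx1 (-2.47 ± 0.16), while Fas was at -0.57 ± 0.41. Cdkn2a, given above as a tumour suppressor gene, stands on this list and was 1 of the 2 that rose. The number that rose was 4 without osteosarcoma line 3. Of 27 interferon response genes, 17 fell, and 23 fell adjusted over the list alone (adjusted p = 9.62e-08, and adjusted p = 0.650 with an estimated correlation), with the interferon regulatory factor Irf7 at -3.56 ± 0.66 (adjusted p = 0.00577). That count was 9 without pre-osteoblast replicate 1 or with only these groups in the fit, and 10 without pre-osteoblast replicate 3. The lines were not alike for some genes of this list. In lines 1, 2 and 3, Ifit3 was at 12.0, 9.93 and 7.78 and Usp18 at 11.4, 9.87 and 7.48. Of 20 hypoxia and glycolysis genes, 10 rose, the same adjusted over the list alone (adjusted p = 1.92e-05, and adjusted p = 0.440 with an estimated correlation). Among them were the hydroxylase Egln3 (2.39 ± 0.31) and the kinase Pdk1 (1.12 ± 0.21); 6 rose without pre-osteoblast replicate 3 and 1 fell without osteosarcoma line 3. BMP and TGF-beta signalling gave 15 of 35 higher and 2 lower, and 17 and 2 adjusted over the list alone (adjusted p = 2.72e-04, and adjusted p = 0.615 with an estimated correlation). Among them were the receptor Bmpr1b (1.68 ± 0.20) and Chrdl1 (1.72 ± 0.35).

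Of 22 imprinted genes, 9 rose and 1 fell, and 10 and 1 adjusted over the list alone (adjusted p = 0.00441, and adjusted p = 0.615 with an estimated correlation), with Ndn at 3.59 ± 0.51, Dlk1 at 2.69 ± 0.51, Dio3 at 2.53 ± 0.38 and the growth factor Igf2 at -2.75 ± 0.34. Of 26 fibroblast and stromal markers, 9 rose and 4 fell, the same adjusted over the list alone (adjusted p = 0.0110, and adjusted p = 0.650 with an estimated correlation). Among them were Cd34 (4.38 ± 0.32), Mfap5 (4.39 ± 0.50) and Dpt (3.98 ± 0.62), with 2 falling without pre-osteoblast replicate 1, and the call was lost without osteosarcoma line 3 (adjusted p = 0.0522). Wnt ligands and receptors gave 7 of 44 higher and 1 lower, and 6 and 1 adjusted over the list alone (adjusted p = 0.00442, and adjusted p = 0.650 with an estimated correlation). Among them were Wnt5a (3.08 ± 0.19), Rspo3 (1.87 ± 0.26) and Fzd3 (1.46 ± 0.05). The number higher was 11 with the arrays centred on their medians and with quantile normalization again, and 2 were lower without osteosarcoma line 1 or pre-osteoblast replicate 1 or 2.

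Further lists were called between osteosarcoma and pre-osteoblasts. E2F targets and DNA replication genes gave 8 of 45 higher, 5 adjusted over the list alone (adjusted p = 3.11e-05, and adjusted p = 0.650 with an estimated correlation). Among them were Slbp (1.04 ± 0.16) and thymidylate synthase, Tyms (1.00 ± 0.19). That count was 15 without pre-osteoblast replicate 2 and 5 without osteosarcoma line 2, osteoblast replicate 1 or pre-osteoblast replicate 1 or 3. Mitosis genes gave 2 of 35 higher, 0 adjusted over the list alone (adjusted p = 0.00560, and adjusted p = 0.746 with an estimated correlation); the count was 0 without osteosarcoma line 1 or 2, osteoblast replicate 3 or pre-osteoblast replicate 1 or 3, 1 without osteoblast replicate 1 and 5 without osteoblast replicate 2. The mitosis call was lost without osteosarcoma line 2 (adjusted p = 0.0628) or pre-osteoblast replicate 1 (0.191). Bone matrix and mineralisation genes gave 4 of 30 higher, 3 adjusted over the list alone (adjusted p = 0.0184, and adjusted p = 0.650 with an estimated correlation), of which Pdpn (1.32 ± 0.10) kept its call under every alternative. The count was 2 without pre-osteoblast replicate 1 and 1 without replicate 2 or 3, and the call was lost without osteosarcoma line 3 (adjusted p = 0.0952) or pre-osteoblast replicate 2 (0.0574). Cholesterol synthesis gave 7 of 19 lower, the same adjusted over the list alone (adjusted p = 0.00691, and adjusted p = 0.650 with an estimated correlation). Among them were Lss (-1.16 ± 0.23) and Nsdhl (-1.12 ± 0.15); the count was 12 without osteoblast replicate 2 and 4 without pre-osteoblast replicate 1 or 3. Adipocyte markers gave 5 of 15 lower, 8 adjusted over the list alone (adjusted p = 0.00836, and adjusted p = 0.650 with an estimated correlation), with Plin4 at -2.99 ± 0.21 and the adipogenic regulator Pparg at -1.54 ± 0.22; it was 3 without pre-osteoblast replicate 1. Genes of protein folding and secretion in the endoplasmic reticulum gave 8 of 24 higher and 3 lower, 9 and 3 adjusted over the list alone (adjusted p = 0.0149, and adjusted p = 0.650 with an estimated correlation), with Pdia6 at 0.80 ± 0.10. The number higher was 5 without osteosarcoma line 1 or pre-osteoblast replicate 1 and 3 without pre-osteoblast replicate 3. This call was lost without osteosarcoma line 1 (adjusted p = 0.0664) or 3 (0.0598). The Wnt antagonists gave 1 of 24 higher, the same adjusted over the list alone (adjusted p = 0.565), the member being Apcdd1 (1.47 ± 0.29). The median was -0.01, the mean 0.09 and the test upward, and the median turned positive with the arrays centred or normalized again. Without osteosarcoma line 2, 5 were higher, and 1 was lower without osteosarcoma line 2 or 3 or osteoblast replicate 2.

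Lists without a call between osteosarcoma and pre-osteoblasts also held changed genes. Of 15 osteoblast transcription factors, 4 rose and 1 fell, 4 and 2 adjusted over the list alone (adjusted p = 0.341), with Zfp521 at 3.57 ± 0.19, Mef2c at 1.71 ± 0.32 and Twist1 at 0.82 ± 0.13. The number that fell was 2 without osteoblast replicate 2 or 3, 3 without osteosarcoma line 2 and 0 without pre-osteoblast replicate 2 or 3. Of 21 beta-catenin target genes, 2 rose and 3 fell, 3 and 3 adjusted over the list alone (adjusted p = 0.820). Tnfrsf11b fell by 2.66 (SE 0.43) and Bmp4 changed by -1.30 ± 0.20, while Myc rose by 1.14 ± 0.14. Their median was -0.03, positive with the arrays centred or normalized again, their mean -0.18 and the test upward. Without osteosarcoma line 2, 4 rose, and without pre-osteoblast replicate 1, 1 rose and 2 fell. In the Notch pathway 4 of 20 were lower and 1 higher, 6 and 2 adjusted over the list alone (adjusted p = 0.232), with the receptors Notch3 at -2.22 ± 0.08 and Notch1 at -1.48 ± 0.12. The rise was lost without osteosarcoma line 2, osteoblast replicate 1 or any 1 pre-osteoblast replicate, and 2 rose without osteosarcoma line 1. Osteoclast regulators gave 3 of 15 higher and 3 lower, 5 and 4 adjusted over the list alone (adjusted p = 0.673), with Efnb2 at 1.52 ± 0.21, a list median of 0.09, a mean of -0.13 and an upward test. The number lower was 1 without osteosarcoma line 2 or pre-osteoblast replicate 2 or 3. Matrix remodelling enzymes gave 4 of 30 higher and 1 lower, 4 and 0 adjusted over the list alone (adjusted p = 0.280), with the collagen hydroxylase genes P4ha3 at 2.03 ± 0.34 and Plod2 at 1.69 ± 0.11. Without osteosarcoma line 2, 7 were higher and the list was called up (adjusted p = 0.00790), 4 were lower without line 1 and 2 without line 3, and the fall was lost without osteoblast replicate 1 or 2 or any 1 pre-osteoblast replicate.

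Of 18 genes of the DNA methylation machinery, 3 rose and 4 fell in osteosarcoma against pre-osteoblasts, 6 and 4 adjusted over the list alone (adjusted p = 0.429). The demethylation enzyme Tet1 was at -1.53 ± 0.18, Apobec1 at -1.43 ± 0.17 and the methyl-DNA binding gene Mbd2 at 0.61 ± 0.05. Hox genes gave 2 of 37 higher and 6 lower, the same adjusted over the list alone (adjusted p = 0.717), with Hoxd8 at 1.34 ± 0.15 and Hoxc13 at -1.83 ± 0.30. Their median of -0.04 turned positive with the arrays centred or normalized again, and 1 was higher without pre-osteoblast replicate 1 or 3. Cyclins, CDK inhibitors and p53 and RB family genes gave 3 of 17 higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.341). Besides Cdkn2a, its neighbour Cdkn2b was at 1.03 ± 0.15, Trp63 at -1.87 ± 0.11 and Rbl2 at -0.55 ± 0.05. Reference genes gave 2 of 12 higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.411), with Pgk1 at 0.89 ± 0.12. The number higher was 1 without osteosarcoma line 1 or pre-osteoblast replicate 1 or 3, and the fall was lost without pre-osteoblast replicate 3. Of 8 sex-linked transcripts, 0 were called by limma, also adjusted over the list alone (adjusted p = 0.280). Before adjustment 3 were higher at a p below 0.05. Without osteosarcoma line 1, 3 were called higher, and the list was called up (adjusted p = 0.0151).

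The spread between the lines was wider than between Kusa4b10 cultures, and the pooled fit then called unchanged simulated genes more often than planned. In simulated data with each group's own spread, 35.7% of the calls between osteosarcoma and pre-osteoblasts and 29.6% of those between osteosarcoma and osteoblasts were false, against 9.73% and 17.1% with only the compared groups in the fit. With only the compared groups, 3566 and 4503 genes were called in the data.

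Osteosarcoma lines were also compared with osteoblasts. Higher in the lines were the mitotic kinesin gene Kif20a at 3.21 ± 0.30 (9.25-fold, adjusted p = 2.27e-04) and Idi1 at 3.12 ± 0.32. Lower in the lines were Car3 at -7.02 ± 0.17 (adjusted p = 1.50e-06), Ibsp at -6.18 ± 0.45, Adipoq at -6.10 ± 0.52, Cd36 at -5.25 ± 0.33, Retn at -4.60 ± 0.16 and Phex at -4.54 ± 0.39. The largest rises were the smooth muscle calponin gene Cnn1 (4.82 ± 0.37, 28.2-fold), Thy1 (4.82 ± 0.30), Cdkn2a, Arhgdib (4.33 ± 0.21), Cd34 (4.28 ± 0.32) and Igfbp6 (4.14 ± 0.15), and Igf2 was lower (-4.43 ± 0.34), as were Lum (-4.79 ± 0.49) and Srgn (-4.60 ± 0.29). All 3 lines lay on the same side of all 3 osteoblast cultures for these genes.

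In this comparison 5459 genes changed (27.4%), 2936 higher and 2523 lower in osteosarcoma, so that 53.8% of the calls were higher; with the arrays centred on their medians 3682 were higher and 2028 lower, or 64.5% higher. All 35 mitosis genes rose, also when adjusted over the list alone, by a median of 2.44 (adjusted p = 7.01e-21, and adjusted p = 0.482 with an estimated correlation), with Ncapg at 3.11 ± 0.34. Of 45 E2F targets and DNA replication genes, 41 rose, and 43 adjusted over the list alone (adjusted p = 4.17e-19, and adjusted p = 0.482 with an estimated correlation). Among them were Rrm2 (2.71 ± 0.40) and Mcm6 (2.25 ± 0.22). Of 19 cholesterol synthesis genes, 17 rose, the same adjusted over the list alone (adjusted p = 6.25e-13, and adjusted p = 0.412 with an estimated correlation). One of them was Stard4 (3.02 ± 0.14). Of 15 adipocyte markers, 14 fell, and 15 adjusted over the list alone (adjusted p = 2.31e-12, and adjusted p = 0.412 with an estimated correlation). Of 24 genes of protein folding and secretion in the endoplasmic reticulum, 21 fell and 2 rose, and 22 and 2 adjusted over the list alone (adjusted p = 9.37e-11, and adjusted p = 0.412 with an estimated correlation). One of those that fell was Ddit3 (-2.54 ± 0.25). Osteoblast cultures had the lower levels of mitosis genes and the higher levels of adipocyte markers in these data, as given above, and osteoblast replicate 2 had the highest mitosis levels of its group.

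Reference genes gave 7 of 12 higher, the same adjusted over the list alone (adjusted p = 0.00268, and adjusted p = 0.412 with an estimated correlation), with Polr2a at 0.75 ± 0.09. Of 40 p53 target genes, 15 fell and 7 rose, the same adjusted over the list alone (adjusted p = 0.0286, and adjusted p = 0.544 with an estimated correlation). Among them were Cd80 (-3.94 ± 0.35) and Trp53inp1 (-2.21 ± 0.29), while Cdkn2a was 1 of the 7 that rose. The number that rose was 4 without osteosarcoma line 1 or osteoblast replicate 1 or 2. The call was lost without osteosarcoma line 2 (adjusted p = 0.0715) or 3 (0.0995). BMP and TGF-beta signalling gave 14 of 35 higher and 6 lower, 15 and 7 adjusted over the list alone (adjusted p = 0.0402, and adjusted p = 0.544 with an estimated correlation), with Tgfbi at 3.09 ± 0.52, Id2 at 2.97 ± 0.17 and Tgfb1 at -1.78 ± 0.11. That call was lost without osteosarcoma line 3 (adjusted p = 0.0995) or osteoblast replicate 1 (0.0504) or 3 (0.0801). Of 21 beta-catenin target genes, 8 fell and 1 rose, 10 and 1 adjusted over the list alone (adjusted p = 0.0414, and adjusted p = 0.544 with an estimated correlation). Among them were the osteoclast inhibitor osteoprotegerin, Tnfrsf11b (-2.64 ± 0.43), and the gap junction gene Gja1 (-1.76 ± 0.26); 2 rose without osteosarcoma line 1. The list lost its call without osteosarcoma line 2 (adjusted p = 0.0981), osteoblast replicate 2 (0.103) or pre-osteoblast replicate 1 (0.0536). Interferon response genes gave 3 of 27 lower, 2 adjusted over the list alone (adjusted p = 0.0286, and adjusted p = 0.783 with an estimated correlation), with Bst2 at -1.88 ± 0.40; the count was 12 without osteosarcoma line 1, and 1 rose without pre-osteoblast replicate 2. The interferon call was lost without osteosarcoma line 2 (adjusted p = 0.106) or 3 (0.245) or osteoblast replicate 1 (0.0504) or 3 (0.0801). Bone matrix and mineralisation genes gave 9 of 30 lower and 2 higher, 9 and 5 adjusted over the list alone, without a call for the list (adjusted p = 0.120), with Dmp1 at -4.30 ± 0.18 and Phospho1 at -3.52 ± 0.21. The number higher was 5 without osteoblast replicate 2 and 1 without osteoblast replicate 1 or 3, and the list was called down without osteoblast replicate 3 (adjusted p = 0.0250). Wnt antagonists gave 4 of 24 lower and 1 higher, the same adjusted over the list alone (adjusted p = 0.522): besides Wif1, these were Nkd2 (-2.21 ± 0.38), Dkk1 (-0.66 ± 0.13), Sost (-0.48 ± 0.10) and Sfrp2 (1.60 ± 0.31). Without osteosarcoma line 2, 5 were higher, and 2 were higher without osteoblast replicate 2.

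The remaining lists gave no call between osteosarcoma and osteoblasts. Of 15 osteoblast transcription factors, 3 rose and 4 fell, the same adjusted over the list alone (adjusted p = 0.905), with Zfp521 at 2.02 ± 0.19, Hey1 at -2.09 ± 0.14 and Dlx3 at -1.17 ± 0.09. Wnt ligands and receptors gave 8 of 44 higher and 7 lower, the same adjusted over the list alone (adjusted p = 0.795), with Wnt5a at 2.37 ± 0.19, Fzd3 at 1.53 ± 0.05 and the receptor Lgr5 at -1.45 ± 0.34. Their median was slightly negative, their mean 0.05 and the test upward, and the median turned positive with the arrays centred or normalized again. The Notch pathway gave 6 of 20 lower, the same adjusted over the list alone (adjusted p = 0.0960), with Notch3 at -2.03 ± 0.08 and the ligand Jag1 at -1.83 ± 0.30. The median of -0.04 turned positive with the arrays centred or normalized again, and 1 was higher without osteoblast replicate 2 or 3. Osteoclast regulators gave 2 of 15 higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.795), with Efnb2 at 1.16 ± 0.21 and Sema3a at -1.35 ± 0.24, and 5 were higher without osteosarcoma line 2. Matrix remodelling enzymes gave 5 of 30 higher and 9 lower, the same adjusted over the list alone (adjusted p = 0.795), with Mmp11 at -2.51 ± 0.36 and P4ha3 at 1.86 ± 0.34. Their median of -0.06 turned positive with the arrays centred, and 5 were lower without osteoblast replicate 3 or pre-osteoblast replicate 1. Hypoxia and glycolysis genes gave 8 of 20 higher and 4 lower, 9 and 5 adjusted over the list alone (adjusted p = 0.222), with Egln3 at 2.08 ± 0.31 and Vegfa at -1.11 ± 0.16.

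Imprinted genes gave 8 of 22 higher and 2 lower in osteosarcoma against osteoblasts, the same adjusted over the list alone (adjusted p = 0.100), with Ndn at 3.60 ± 0.51 and Peg10 at 2.93 ± 0.37. The imprinted genes and the fibroblast and stromal markers were called up without osteosarcoma line 2 (adjusted p = 0.0227 for both lists). Of 18 genes of the DNA methylation machinery, 5 rose and 4 fell, the same adjusted over the list alone (adjusted p = 0.740). Uhrf1, which brings the maintenance methyltransferase to DNA, was at 2.13 ± 0.31, Dnmt1 at 1.91 ± 0.21 and Gadd45a at -2.86 ± 0.33, and the list median of 0.02 turned negative with quantile normalization again. Hox genes gave 5 of 37 higher and 3 lower, the same adjusted over the list alone (adjusted p = 0.668), with Hoxd8 at 1.31 ± 0.15. The number higher was 8 without osteosarcoma line 3, 3 without line 1 or osteoblast replicate 1, and 2 without osteoblast replicate 2 or 3. The number of Hox genes lower was 5 without line 1 and 2 without osteoblast replicate 1. Fibroblast and stromal markers gave 9 of 26 higher and 6 lower, 10 and 7 adjusted over the list alone (adjusted p = 0.227). Cyclins, CDK inhibitors and p53 and RB family genes gave 8 of 17 higher and 3 lower, the same adjusted over the list alone (adjusted p = 0.199), with Cdkn2b at 1.33 ± 0.15 and Rbl1 at 1.21 ± 0.16. Of 8 sex-linked transcripts, 1 was higher, 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.199). That member was the X-linked gene Kdm5c at 0.53 ± 0.10, and 2 were higher without osteosarcoma line 3. Without line 1, 4 were higher and 1 lower, and the list was called up (adjusted p = 0.00849).

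**Figure D2:**
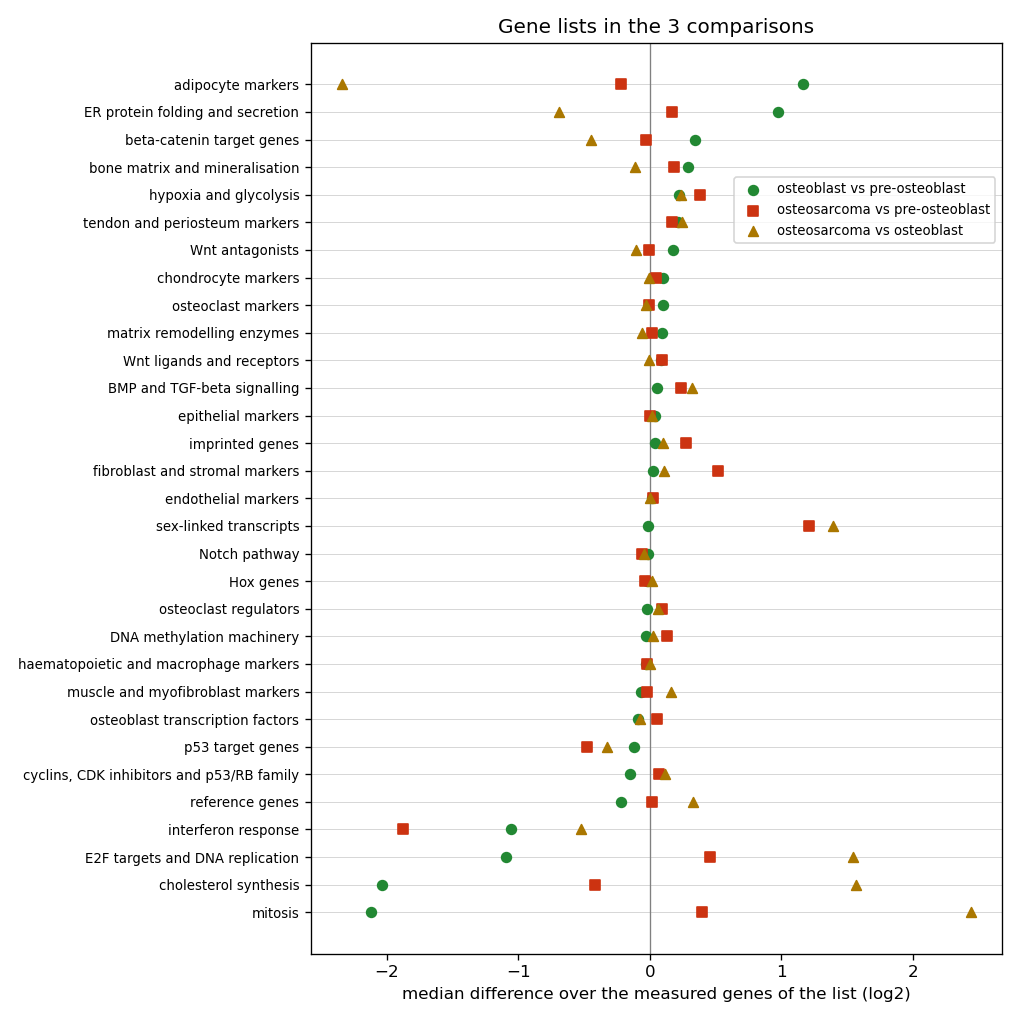
Median log2 difference over the measured genes of each of the 31 gene lists (vertical axis), with log2 difference on the horizontal axis. Circles compare osteoblasts with pre-osteoblasts, squares osteosarcoma with pre-osteoblasts and triangles osteosarcoma with osteoblasts. The mitosis list lies at -2.12 in the first of these and at 2.44 in the last.

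Genes that changed between pre-osteoblast and osteoblast cultures were followed into the tumour lines. Of the 501 genes at least 2-fold higher in osteoblasts than in pre-osteoblasts, 196 were also higher in osteosarcoma than in pre-osteoblasts, 18 were lower and 287 did not pass. Of the 742 genes at least 2-fold lower in osteoblasts, 298 were also lower in osteosarcoma, 28 were higher and 416 did not pass. Set against osteoblasts, 373 of the 501 genes (74.5%) were lower in osteosarcoma and 514 of the 742 (69.3%) were higher. These genes were selected on the same osteoblast arrays, and simulated osteosarcoma groups at the osteoblast means gave mean shares of 4.14% and 3.10%. Those shares show what the selection alone brings when no gene differs between osteosarcoma and osteoblasts. They do not show what an unrelated line would give. Osteoblast cultures were kept for 21 days in medium with ascorbate, while the lines were grown subconfluent. All 35 measured mitosis genes fell in osteoblasts and were higher in osteosarcoma than in osteoblasts. In the shares of 74.5% and 69.3%, differentiation therefore cannot be told apart from growth state. Of all 19938 genes, 2523 were called lower and 2936 higher in osteosarcoma than in osteoblasts. Over all genes, 667 were higher and 1364 lower in both osteoblasts and osteosarcoma, 140 were higher in osteoblasts and lower in osteosarcoma, and 184 the reverse. Independent lists would share 204 higher and 427 lower genes, with 277 and 314 in opposite directions. Simulated unchanged groups that share the pre-osteoblast arrays gave means of 0 and 0.02 genes, but unchanged groups yield almost no calls, so these means do not show what shared arrays bring between groups that differ. Without pre-osteoblast replicate 3, 387 were higher in both, and the genes in opposite directions, 324 in all, numbered 139 without pre-osteoblast replicate 3, 181 without replicate 1, 202 without replicate 2, 189 without osteoblast replicate 1 and 191 without osteoblast replicate 3. The fold changes had a covariance of 0.117 against a simulated 0.0136, and a correlation across genes, which are not independent replicates, of 0.400 against a simulated 0.499. The simulated correlation was the higher one, but unchanged groups correlate at that level through the shared arrays alone. It therefore cannot judge the correlation of groups that differ. The pre-osteoblast arrays were then split, 1 for one comparison and 2 for the other, in all 6 ways, a test chosen after the data were examined in which a lone array is assumed to vary like the other groups. With no array shared, 268 to 320 genes were higher in both, 520 to 869 lower in both and 67 to 264 opposite, where independent lists would share 52.7 to 85.7, 113 to 260 and 158 to 305. The covariance was 0.0886 to 0.128 and the correlation 0.272 to 0.449. Part of the overlap without the split may come from the shared controls. With the split, both comparisons still subtract the same pre-osteoblast state, so a gene particular to that state counts in both. The second principal component, with 33.8% of the variance, set pre-osteoblasts apart from both other groups. Independent lists therefore cannot judge whether the lines share the changes of differentiation.

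The 3 osteosarcoma lines differed from each other, with 1 array each and no test. A range of at least 2 log2 was found for 223 genes over the lines, 7 over the osteoblast cultures and 8 over the pre-osteoblast cultures. The widest range was that of Xist, the RNA of the inactive X chromosome, at 12.7, 5.27 and 5.56 in lines 1, 2 and 3. The Y-linked gene Eif2s3y was at 3.91, 9.88 and 10.1, and Uty at 4.82, 9.51 and 9.80. The collagen gene Col14a1 was at 11.3, 7.17 and 12.4, the collagenase Mmp13 at 9.33, 7.72 and 12.9, Thbs4 at 8.06, 7.04 and 12.2, and the retinoic acid enzyme Aldh1a2 at 5.80, 7.73 and 10.4. Serpina3n was at 11.5, 7.04 and 11.4, Kng1 at 10.01, 6.39 and 10.9, and Adgrd1 at 11.7, 7.31 and 10.3.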

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

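The counts over probe sets without a gene name came from tests chosen only after the results for named genes were seen, while the splits of the arrays were planned. The gene comparisons left out 12146 probe sets for which the annotation used here gives no gene, and these also differed between the groups. In limma with Benjamini-Hochberg adjustment over all probe sets, 2216 of them changed between osteoblasts and pre-osteoblasts, 1186 of these higher in osteoblasts. Between osteosarcoma and pre-osteoblasts 2364 changed, 714 of them higher in osteosarcoma, and between osteosarcoma and osteoblasts 2662 changed, 812 of them higher in osteosarcoma. Among 1621 probe sets with several gene symbols, 363, 312 and 442 changed in these comparisons.

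Other splits of the arrays were set against the real groups. For each pair of groups there are 10 splits of the 6 arrays, too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes. The real splits gave 5202 genes for osteoblasts against pre-osteoblasts, 4686 for osteosarcoma against pre-osteoblasts and 5459 for osteosarcoma against osteoblasts, and the highest other split gave 0 in each. For any difference among the 3 groups, 100 of the 280 splits of the 9 arrays were used, the real one and others drawn at random. Only the real one gave as many genes (7663). The highest other split gave 2230, so a random grouping of the arrays can be excluded for that test. Which difference between the groups the genes follow, such as line, tumour state or culture, cannot be told from these splits.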

How the results depend on the processing

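The only tests in this part chosen after the results were seen are those that leave out osteoblast replicate 2 together with pre-osteoblast replicate 2. For every result below that changed, the cause was not tested, except that stricter thresholds pass fewer genes by construction. The counts of changed genes were 5202 for osteoblasts against pre-osteoblasts, 4686 for osteosarcoma against pre-osteoblasts, 5459 for osteosarcoma against osteoblasts and 7663 in the F test. At thresholds left as planned they stayed within 1.5 times of these values, from 3542 to 7453, 3364 to 5185, 4058 to 6285 and 5815 to 9555, each highest with 1 weight per array. Leaving out each array in turn gave 3804 to 5881, 3364 to 4686, 4058 to 5618 and 6181 to 7970. With a change of at least 2-fold required, the pairwise counts were 1243, 913 and 1384, and 115 genes were higher in both osteoblasts and osteosarcoma, 181 lower in both and 24 opposite. At an adjusted p below 0.01 the counts were 3105, 2540, 3378 and 5014 in the F test, with 307, 717 and 86 in the overlap. The overlap of 667, 1364 and 324 genes gave 387 to 730, 989 to 1503 and 139 to 386 with each array left out in turn, 594 opposite with 1 weight per array, and 396 higher and 902 lower in both with osteoblast replicate 2 and pre-osteoblast replicate 2 left out. The share of calls higher in osteosarcoma than in pre-osteoblasts was 42.4%, 51.3% with quantile normalization again and 51.7% with the arrays centred. Camera with an estimated correlation called 0 lists in each comparison, against 11, 13 and 10, with unadjusted counts of 3, 1 and 3. Leaving out each array in turn gave 8 to 12, 10 to 14 and 7 to 12 called lists.

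Wif1 between osteoblasts and pre-osteoblasts kept its direction in all alternatives, with adjusted p from 0.0163 to 0.109. With each array left out in turn the difference was 1.04 to 2.05. It was 1.71 with only the compared groups in the fit (adjusted p = 0.0566) and with the replicate block (0.0574), and 0.99 with osteoblast replicate 2 and pre-osteoblast replicate 2 left out (0.0712). Between osteosarcoma and osteoblasts Wif1 also kept its direction, at -2.08 to -1.08 with each array left out in turn, with adjusted p from 0.0191 to 0.0989 over the alternatives. It was -1.74 with only the compared groups in the fit (adjusted p = 0.0945) and with 1 weight per group (0.0740). The filter at the median level removed Wif1, so no value was had there. Low levels also limit other dim genes, since differences near background are compressed. A reversal was counted where the sign changed and the gene was called in the main fit or in the alternative. Sign changes without a call, as for Wif1 between osteosarcoma and pre-osteoblasts, were not counted. Among the named genes of all comparisons, only the difference of Igfbp4 between osteosarcoma and pre-osteoblasts reversed in this sense. It was -0.46 (adjusted p = 0.796), with -1.25 to 0.89 over the left-out arrays, and 0.89 without osteosarcoma line 2 (adjusted p = 0.0108, against 0.0108 to 0.981 over the alternatives).

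Of the named genes tested, 170 between osteoblasts and pre-osteoblasts, 165 between osteosarcoma and pre-osteoblasts and 162 between osteosarcoma and osteoblasts, some lost or gained a call. With only the compared groups in the fit, 3, 14 and 12 lost their call and 13, 4 and 1 gained one. With 1 weight per array 0, 0 and 1 lost it and 21, 15 and 18 gained one. Without osteosarcoma line 2, 2, 9 and 8 lost it and 10, 11 and 11 gained one, besides the reversal. With both replicates 2 left out 26, 15 and 14 lost it and 3, 7 and 4 gained one, and the counts of changed genes were 3542, 3369 and 4353. Of 186 list counts, 34 moved by over 1.5 times with 1 weight per array, 15 with 1 weight per group, 12 with the arrays centred, 16 with quantile normalization again, 28 with only the compared groups, 24 with the filter at the median and 49 with both replicates 2 left out. The number of genes with a range of at least 2 over the lines was 223, or 221 with the mean of the probe sets.

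The replicate numbers of the osteoblast and pre-osteoblast cultures were checked for pairing. Deviations from the group means correlated at 0.152, 0.176 and 0.0278 between cultures of number 1, 2 and 3. Between cultures of different numbers the correlations ran from -0.160 to 0.0766. With so few cultures, these values do not settle whether the numbers pair the samples. Osteoblast replicate 3 correlated best with pre-osteoblast replicate 1 (0.0766) and the other osteoblast cultures with their own number. The fit with the replicate block held only the Kusa4b10 arrays and called 5883 genes and 12 lists. The same groups fitted without the block gave 6316 genes and 12 lists, and the main fit of all 9 arrays 5202 and 11. The block therefore did not raise these counts. Between the block fit and the main fit, 5 of the 170 named genes lost their call and 18 gained one, and 7 of 62 list counts moved by over 1.5 times.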

Other observations

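The tests of explanations in this part were all chosen after the results were seen, while the marker lists and their counts were planned. Of the lists of markers of further cell types in this part, none was called by camera in any comparison of the main fit. A list could still shift in its mean. Tendon and periosteum markers had a mean of 0.82 and a median of 0.17 between osteosarcoma and pre-osteoblasts. That list held Col14a1 and Thbs4, whose ranges over the osteosarcoma lines were among the widest. Of 20 muscle and myofibroblast markers, 7 were lower in osteoblasts than in pre-osteoblasts, the same adjusted over the list alone (list median -0.07, adjusted p = 0.207), a number that was 3 without osteoblast replicate 1 or pre-osteoblast replicate 1, 2 without osteoblast replicate 3 and 4 without pre-osteoblast replicate 2. In osteosarcoma 2 were higher than in pre-osteoblasts, the same over the list alone (adjusted p = 0.636), namely the calponin gene Cnn1 (3.32 ± 0.37) and Synpo2 (0.85 ± 0.15), and 3 were higher and 1 lower without osteoblast replicate 2. The median of that comparison was -0.02, the mean 0.14 and the test upward, and the median was positive with the arrays centred or normalized again. Against osteoblasts 5 were higher, the same over the list alone, among them Cnn1 (4.82 ± 0.37) and the smooth muscle gene Tagln (2.03 ± 0.43). That list test (adjusted p = 0.0780) passed without osteosarcoma line 1 (adjusted p = 0.0481) or osteoblast replicate 2 (0.0184). Of 19 chondrocyte markers, 3 were higher in osteoblasts than in pre-osteoblasts, the same over the list alone (adjusted p = 0.0711), with Matn4 at 0.68 ± 0.11. Without osteoblast replicate 1 only 1 was higher, 1 was lower without osteoblast replicate 2 or osteosarcoma line 3, and the list passed without osteosarcoma line 2 (adjusted p = 0.0490) or osteoblast replicate 3 (0.0346). Osteosarcoma against pre-osteoblasts gave 1 higher and 2 lower, the same over the list alone (adjusted p = 0.308), with Sox5 at -0.84 ± 0.12. There 0 were higher without osteosarcoma line 1 or 3 or any 1 pre-osteoblast replicate and 3 without osteosarcoma line 2, and 1 was lower without osteosarcoma line 1 or 2 or pre-osteoblast replicate 1 or 2. Against osteoblasts 3 chondrocyte markers were lower, the same over the list alone (adjusted p = 0.516), with Col10a1 at -3.40 ± 0.53, and 2 were higher without osteosarcoma line 2; the median of -0.01 was positive with the arrays centred or normalized again.

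Of 14 tendon and periosteum markers, 3 were higher and 1 lower in osteoblasts than in pre-osteoblasts, the same adjusted over the list alone (adjusted p = 0.241), with Prrx1 at -0.67 ± 0.11; 1 was higher without osteoblast replicate 2 or pre-osteoblast replicate 2 or 3. Osteosarcoma against pre-osteoblasts gave 2 higher, 1 over the list alone (adjusted p = 0.160), with periostin, Postn, at 2.26 ± 0.37. That number was 1 without osteoblast replicate 1 or 3 or pre-osteoblast replicate 2 or 3, 1 was lower without osteosarcoma line 2 or osteoblast replicate 2, and the list passed without osteosarcoma line 2 (adjusted p = 0.0499). Against osteoblasts 2 were higher and 2 lower, 2 and 3 over the list alone (adjusted p = 0.709), with the protease gene Ctsk at -1.65 ± 0.34. There 0 were higher without osteoblast replicate 1 or 3 or any 1 pre-osteoblast replicate and 1 without osteosarcoma line 1, and 1 was lower without osteosarcoma line 1, osteoblast replicate 2 or 3 or pre-osteoblast replicate 1. Of 11 osteoclast markers, 4 were higher and 2 lower in osteoblasts than in pre-osteoblasts, the same over the list alone (adjusted p = 0.259), with Atp6v0d2 at 1.74 ± 0.19 and Itgb3 at 1.68 ± 0.18. Osteosarcoma gave 2 higher and 1 lower against pre-osteoblasts (adjusted p = 0.655) and 1 and 3 against osteoblasts (adjusted p = 0.635), the same over the list alone, with Acp5 at 1.06 ± 0.10 and 0.70 ± 0.10. Against pre-osteoblasts 1 was higher without osteoblast replicate 3 or any 1 pre-osteoblast replicate and 2 were lower without osteosarcoma line 1 or osteoblast replicate 2, and against osteoblasts 2 were higher without osteoblast replicate 2. Both medians, -0.01 and -0.03, were positive with the arrays centred or normalized again.

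Of 15 endothelial markers, 1 was higher and 1 lower in each comparison, with adjusted p of 0.832, 0.280 and 0.466, the same over the list alone except that 0 were lower in osteosarcoma than in pre-osteoblasts. Endoglin, Eng, was 2.84 ± 0.09 higher in osteosarcoma than in pre-osteoblasts and 3.00 ± 0.09 higher than in osteoblasts. The rise between osteoblasts and pre-osteoblasts was lost without osteoblast replicate 1 or 3 or pre-osteoblast replicate 1 or 2. The fall between osteosarcoma and pre-osteoblasts was lost without any 1 osteosarcoma line or pre-osteoblast replicate, and 2 were higher in both osteosarcoma comparisons without osteosarcoma line 2. Of 20 haematopoietic and macrophage markers, limma called 1 lower in osteoblasts than in pre-osteoblasts (0 over the list alone, adjusted p = 0.926) and 0 in osteosarcoma against pre-osteoblasts, also over the list alone (adjusted p = 0.820). In the latter 1 was higher and 1 lower at an unadjusted p below 0.05. Against osteoblasts 1 was higher and 1 lower, the same over the list alone (adjusted p = 0.795). The first of these calls was lost without osteoblast replicate 1 or 2 or pre-osteoblast replicate 1, and 1 was higher in osteosarcoma than in pre-osteoblasts without osteoblast replicate 2. Against osteoblasts 2 were higher without osteosarcoma line 2 or 3 and 0 lower without osteoblast replicate 2 or 3. Of 13 epithelial markers, limma called 0 in osteoblasts against pre-osteoblasts (3 lower at an unadjusted p below 0.05, adjusted p = 0.852 for the list) and 0 in osteosarcoma against pre-osteoblasts (0 unadjusted, adjusted p = 0.717). Against osteoblasts it called 1 higher, 0 over the list alone (adjusted p = 0.833), a call kept only where the array left out was that of osteosarcoma line 3. Without osteosarcoma line 2 or 3 or osteoblast replicate 2, 1 was lower in osteoblasts than in pre-osteoblasts, and without osteosarcoma line 3, 1 was higher in osteosarcoma than in pre-osteoblasts. Of the lists of this part, tendon shares 2 genes with another list, osteoclast 2 and endothelial 1.

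Wif1 stood 2.00 above the mean of the other osteoblast cultures in osteoblast replicate 2. Scaling of that array would have to move other genes as well, but the 12 reference genes had a median deviation of 0.0114 there, which argues against it. If that culture held fewer adipocyte-like cells, osteoblast genes would rise alike, yet the 13 bone matrix genes called higher in osteoblasts had a median deviation of 0.749, below that of Wif1 by more than their SD of 0.732. These genes were picked on the same arrays and spread widely, so their median cannot exclude this for a single gene. The same array had higher mitosis genes (median 1.10) and lower adipocyte markers (-0.40). A culture at another stage of differentiation, or with fewer adipocyte-like cells, may account for part of the Wif1 deviation, and both stay open. The labels give no factor that separates this culture, and no further explanation was tested.

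Line 3 of the osteosarcoma group is labelled female, but its Y-linked transcripts Kdm5d, Eif2s3y and Uty were at 8.76, 10.1 and 9.80 and its Xist at 5.56. Line 2, labelled male, had 8.74, 9.88 and 9.51 with Xist at 5.27, and line 1, labelled female, had 5.12, 3.91 and 4.82 with Xist at 12.7. An exchange of names within the group would leave as many lines with Y-linked transcripts above every Kusa4b10 array as are labelled male, yet there were 2 such lines and 1 male label. RNA of line 2 mixed into line 3 would leave its Y-linked transcripts lower, but their mean was 0.162 higher, and the correlation across genes of lines 2 and 3 (0.982) was below that of the closest pair (0.987). A wrong sex label or a sample from outside the group may account for the values, and the sex of the animals was not tested otherwise.

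Adipocyte markers were higher in osteoblast cultures, with 10 of 15 called and a median difference of 1.16. Levels in osteoblasts were 13.8 for Scd1, 13.4 for Lpl, which was not called, 12.3 for Adipoq, 12.2 for Fabp4 and 11.6 for Retn. Scaling between the groups is argued against by the 12 reference genes, whose median difference was -0.22, opposite in direction. That list was itself called lower in this comparison (camera, adjusted p = 0.0203, and 0.452 with an estimated correlation), so it is not a fixed yardstick. A candidate source is cells with an adipocyte programme in the Kusa4b10 cultures, but the count of 10 markers is the observation itself and decides nothing about it. Pre-osteoblasts already held 8 of the 15 markers above the median level of all genes, among them Scd1 (13.5), Lpl (12.6) and Pparg (11.7), and the list shares 0 genes with the other lists. Whether these transcripts came from separate adipocyte-like cells or from the osteoblasts themselves was not tested, since each array averages over a culture, and the medium and time in culture stay open as untested.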
